A study of Brugia malayi with 68 samples.

How the data were processed

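The series measured messenger RNA in the filarial nematode Brugia malayi taken from infected gerbils that had been given an anthelmintic drug or left untreated. Per the labels' protocols, Mongolian gerbils were infected in the peritoneal cavity and kept until larvae circulated. They then received albendazole at 1 mg/kg, diethylcarbamazine at 6 mg/kg or ivermectin at 0.2 mg/kg, or no drug. Worms were collected 1 or 7 days later and sorted into females, males and microfilariae, the larvae that females release. The labels name the untreated groups after the solvent DMSO while the treatment protocol describes those animals as untreated, so they are called untreated here. Libraries were made with a strand-specific TruSeq kit, per the labels' protocols.

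The deposited table holds raw read counts per gene, 1 column per library, with no normalisation. TopHat2 2.0.14 and HTSeq 0.6.1p1 are listed in the submitters' processing notes. The role of each tool, the genome build, the annotation release and the counting options are not given there. Reads from closely related gene copies may be split between them in such a table, and this could not be examined.

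Each column was joined to its sample by the name in the label. The 68 libraries form 24 groups from 3 stages, 4 treatments and 2 days, with 3 libraries in 20 groups and 2 libraries in the 4 groups of day 7 microfilariae. Total counts per library ran from 2112032 to 37822431, with a median of 13426840. The table lists 11590 gene identifiers. None of them (0) occurs in the reference table of 11688 genes, and the files do not pair identifiers with gene names. The 23 gene lists fixed beforehand (tubulins, ligand-gated ion channels, major sperm proteins, cuticle collagens, ABC transporters, chitinases and others) and the drugs' known target genes therefore could not be looked up, and 0 of the lists were tested. Genes are given by identifier, at most 2 that were higher and 2 that were lower per comparison.

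All computation from the counts was done with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures with Python 3.11.15 and matplotlib 3.10.9. Within each stage all libraries entered one edgeR quasi-likelihood fit of group means, because each group has only 2 or 3 libraries. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, and libraries were scaled by TMM. This left 10264 genes in females, 10347 in males and 10174 in microfilariae. The common biological coefficient of variation was 0.277, 0.207 and 0.189 in that order. Each drug group was set against the untreated group of the same stage and day, which makes 18 comparisons. Further contrasts were untreated day 7 against day 1 in each stage, the difference of each drug's effect between days, and the difference between females and males. The last used 1 fit of all 48 adult libraries with 10693 genes. Untreated females against males, and untreated microfilariae against adults, used 1 fit of the 17 untreated libraries with 10633 genes. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. These comparisons, the tests and the alternatives listed first below were chosen before the data were examined. The rule for genes named in the text takes those past the threshold whose drug libraries all lie above, or all below, all untreated libraries, by smallest p, and, where no names exist, at most 2 per direction. Any gene named outside that rule was chosen after its values were seen, which is stated where it appears.

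A further 4 gene sets, whose rule was also fixed beforehand, came from the untreated libraries themselves. Each of these stage sets holds the 100 genes with the smallest p among those past the threshold and at least 4-fold higher in females than males, in males than females, in microfilariae than adults, or in adults than microfilariae. A comparison used the sets from the untreated groups of the other day. The group means behind the fold changes that chose the genes thus left out the untreated libraries of the tested day. The gene filter, the scaling and the gene-wise spread behind the p-values came from the fit of untreated libraries of both days. The choice of genes is therefore not fully independent of the untreated libraries used to test them. Between 87 and 95 of each set's genes were shared by both days. Sets were tested with camera at a preset correlation of 0.01, adjusted over the 4 sets of a comparison, with camera at an estimated correlation and fry beside it. Set levels are means of log2 CPM with a prior count of 2. Fry asks whether a set's genes move one way on balance and does not compare them with other genes.

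Correlations and covariances of fold changes between drugs share their untreated libraries, so unchanged groups, with no replicate effect, were simulated 20 times against those libraries. The share of variance between libraries by treatment and by replicate number was computed over all genes within a stage and day, with an exact permutation of treatments within replicate numbers. That share, the test of females against males within each drug group, and the test of sets on female-minus-male differences were added after the data were seen.

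The series text describes 3 biological replicates, each of which held all treatments, so replicate numbers pair the libraries of a stage and day by design. Deviations from the group mean correlated across genes between libraries of the same number and day, with a median of 0.42 in females, 0.19 in males and 0.35 in microfilariae, and 80 of 102 such pairs were above 0.1. Medians for the same number on different days were 0.02, 0 and 0.02. For drug and untreated libraries of the same number, 43 of 51 pairs were above 0.1, with values from -0.39 to 0.86. The planned fit with a replicate block was run, and a replicate block within day was added after this check. None (0) of the 64 pairs of libraries compared within groups held identical counts.

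The alternatives chosen then were RLE size factors, DESeq2, no filter on low counts, the replicate block and leaving out each library in turn. Those added after the data were seen were the block within day, and fits without 4 male libraries and without 3 female libraries that stood apart. The pipeline was tested on simulated data drawn from the real means, with 200 genes changed. In the simulation of male day 1 ivermectin with 10302 genes, 69.1% of 2-fold, 92.4% of 4-fold and 98.5% of 8-fold changes were called. For female day 1 diethylcarbamazine with 10224 genes these shares were 38.2%, 84.8% and 93.9%. The simulated spread is the same for every library and holds no replicate effect. These shares may therefore overstate the power where libraries stand apart, which was not simulated.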

Results

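RNA was sequenced from Brugia malayi females, males and microfilariae recovered from gerbils 1 or 7 days after a dose of albendazole, diethylcarbamazine or ivermectin, or after no drug. Albendazole binds worm tubulin, ivermectin opens glutamate-gated chloride channels, and diethylcarbamazine is an antifilarial drug. The question was how each drug alters the worms' gene expression inside the host. The 68 libraries form 24 groups, of which 20 have 3 libraries and the 4 groups of day 7 microfilariae have 2. Total counts per library ran from 2112032 to 37822431 in the 24 female libraries, from 6037954 to 27464745 in the 24 male libraries and from 5867535 to 24449425 in the 20 microfilaria libraries. Between 10261 and 11229 of 11590 genes had at least 1 count per library. The files do not pair gene identifiers with names, so gene groups are described by the stage in which untreated worms express them most.

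Replicate number took more of the variance between libraries than treatment in 4 of the 6 combinations of stage and day. The shares were 57.9% and 14.2% in day 1 females, 37.2% and 22.8% in day 7 females, 32.2% and 21.1% in day 1 males, and 46.9% and 22.2% in day 1 microfilariae. Treatment took more in day 7 males (25.3%, against 19.3% for replicate number) and in day 7 microfilariae (38.4%, against 26.2%). Treatment has more levels than replicate number, which by itself raises its share. With permuted treatments its median share at day 1 and day 7 was 13.6% and 20.9% in females and 22.3% and 26.7% in males. In microfilariae it was 17.5% and 37.3%. The larger treatment shares in day 7 males and day 7 microfilariae are therefore not read as a treatment effect. Day 7 females were the one stage and day with an unadjusted exact permutation p under 0.05 (p = 0.0382, adjusted over 6 stage and day combinations 0.224). The exact permutation p was 0.0747 in day 1 microfilariae (adjusted 0.224) and 0.297 in day 1 females (adjusted 0.594). In males it was 0.562 at day 1 (adjusted 0.674) and 0.701 at day 7 (adjusted 0.701). In day 7 microfilariae it was 0.458 (adjusted 0.674), where the smallest p the design allows is 0.0417. The first principal component of the female libraries, with 47.4% of their variance, set 3 libraries apart: day 1 replicate 3 of the untreated, diethylcarbamazine and ivermectin groups scored 71.3, 90.9 and 71, and no other female library scored above 1.1. Their 100 most abundant genes took 20.7%, 20.8% and 19.7% of counts, against 12.3% in replicate 3 of the albendazole group.

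**Figure D1:**
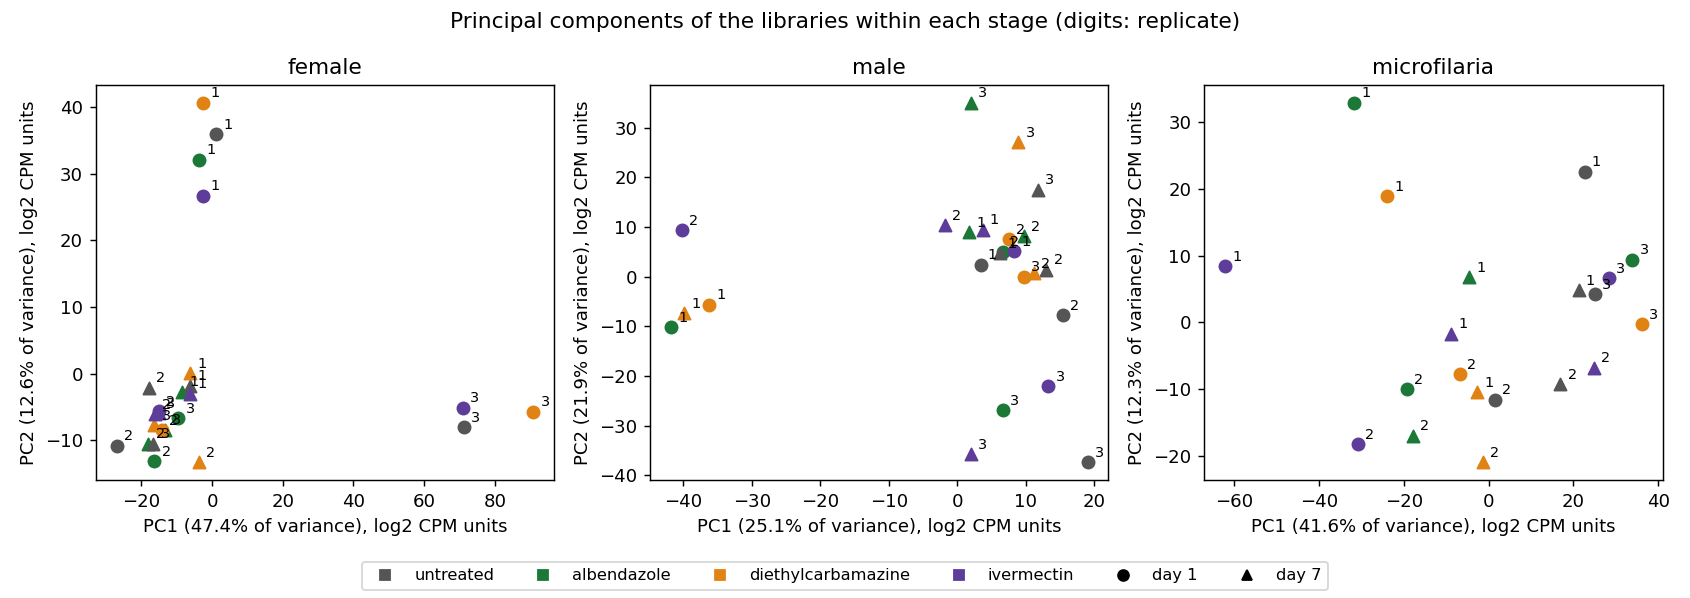
Scores of the libraries on the first 2 principal components of log2 CPM, 1 panel per stage; colour gives the treatment, circles day 1, triangles day 7, and digits the replicate. In females 3 day 1 libraries of replicate 3 lie at 71 to 90.9 on the first component, and the 4 day 1 libraries of replicate 1 lie together on the other axis at 26.7 to 40.6.

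**Figure D2:**
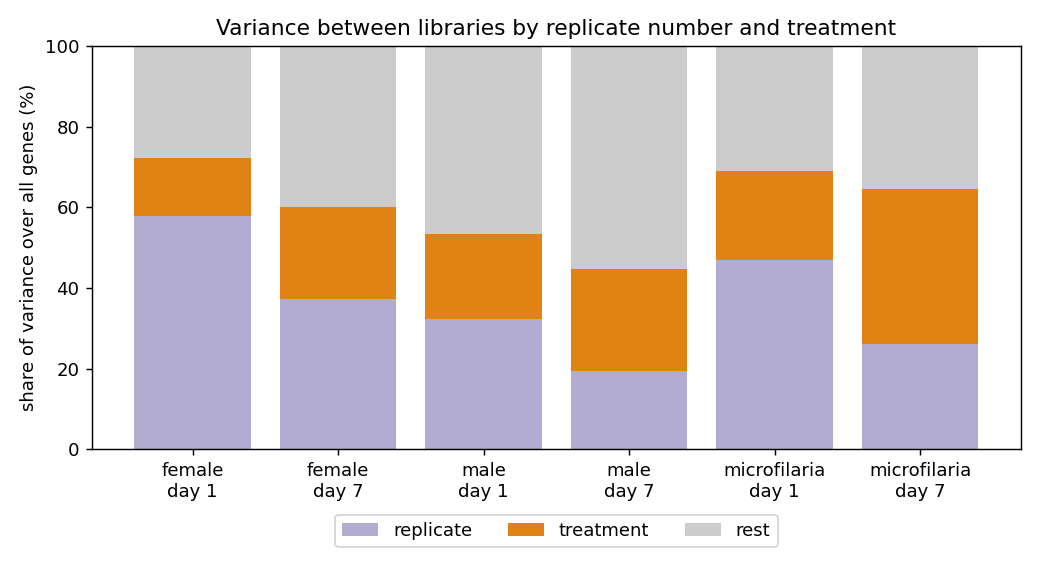
Share of the variance between libraries, summed over all genes, by replicate number, treatment and the rest, in percent, 1 bar per stage and day. The replicate share runs from 19.3% in day 7 males to 57.9% in day 1 females.

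Untreated females and males differed in most genes, so the labels part distinct groups. Which group is which could not be checked, since no sex marker could be looked up by name. Of 10633 genes, 3804 were higher in females and 3929 higher in males by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 7733 in all. At 4-fold or more, 1017 genes were female-biased and 1407 male-biased, and at 16-fold or more 328 and 783. The female-biased gene WBGene00223460 stood at 9.14 ± 0.24 log2 CPM in females and 1.5 ± 0.34 in males (SD, n = 6 each), a log2 fold change of 7.74 (SE 0.18, edgeR adjusted p = 3.8e-14). WBGene00229620 was higher by 8.83 on the log2 scale (SE 0.2). Of the male-biased genes, WBGene00230178 had a log2 fold change of -5.31 (SE 0.15) and WBGene00230114 of -6.12 (SE 0.17), both with an edgeR adjusted p of 1.8e-13. These identifiers, and those in the next paragraph, have the smallest p-values and were chosen after their values were seen.

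Microfilariae and adults were as distinct, with 3433 genes higher in untreated microfilariae and 4127 higher in untreated adults by edgeR's quasi-likelihood test, 7560 in all. WBGene00230037 stood at 10.20 ± 0.29 log2 CPM in microfilariae (SD, n = 5) and 2.43 ± 1.42 in adults (SD, n = 12), a log2 fold change of 7.80 (SE 0.18, edgeR adjusted p = 2.61e-14). WBGene00220302 had a log2 fold change of 11.77 (SE 0.29, edgeR adjusted p = 3.21e-14). The adult genes WBGene00231076 and WBGene00228981 had log2 fold changes of -8.52 (SE 0.19) and -8.40 (SE 0.19). Adults were weighted as the mean of their 4 untreated groups.

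The sex-biased programme was present in every drug group. Of 2413 genes that differed 4-fold or more between untreated sexes and were tested in both fits, between 2411 and 2413 had the same direction in each of the 6 combinations of drug and day. Between 2343 and 2391 of them were also called there by edgeR in that direction, and 1 was called in the other direction, with ivermectin at day 1. Across genes, the slope of the drug groups' sex difference on the untreated one ran from 0.918 (diethylcarbamazine, day 1) to 1.048 (albendazole, day 7). Genes are not independent replicates, so these slopes carry no p-value.

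In all 18 comparisons of a drug with the untreated worms of the same stage and day, edgeR's quasi-likelihood test called 0 genes after adjustment, so the rule for named genes took none. With a replicate block within day, added after the data were seen, it called 18 genes in day 1 microfilariae with ivermectin and 0 in the other comparisons. DESeq2 called 1 gene in day 1 males with diethylcarbamazine and 0 in the other comparisons. That gene, WBGene00223906, had a log2 fold change of -0.40 (SE 0.08, DESeq2 adjusted p = 0.00902) and is named after its value was seen. In each stage, 0 members of the 4 stage sets were called in a drug comparison by edgeR, whether adjusted over all genes tested or adjusted over the list alone. Of the 72 tests of a stage set in a drug comparison, 38 were called by camera with its preset correlation, 4 with an estimated correlation and 0 by fry. The sections below therefore give each set's size together with the p at an estimated correlation.

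**Figure D3:**
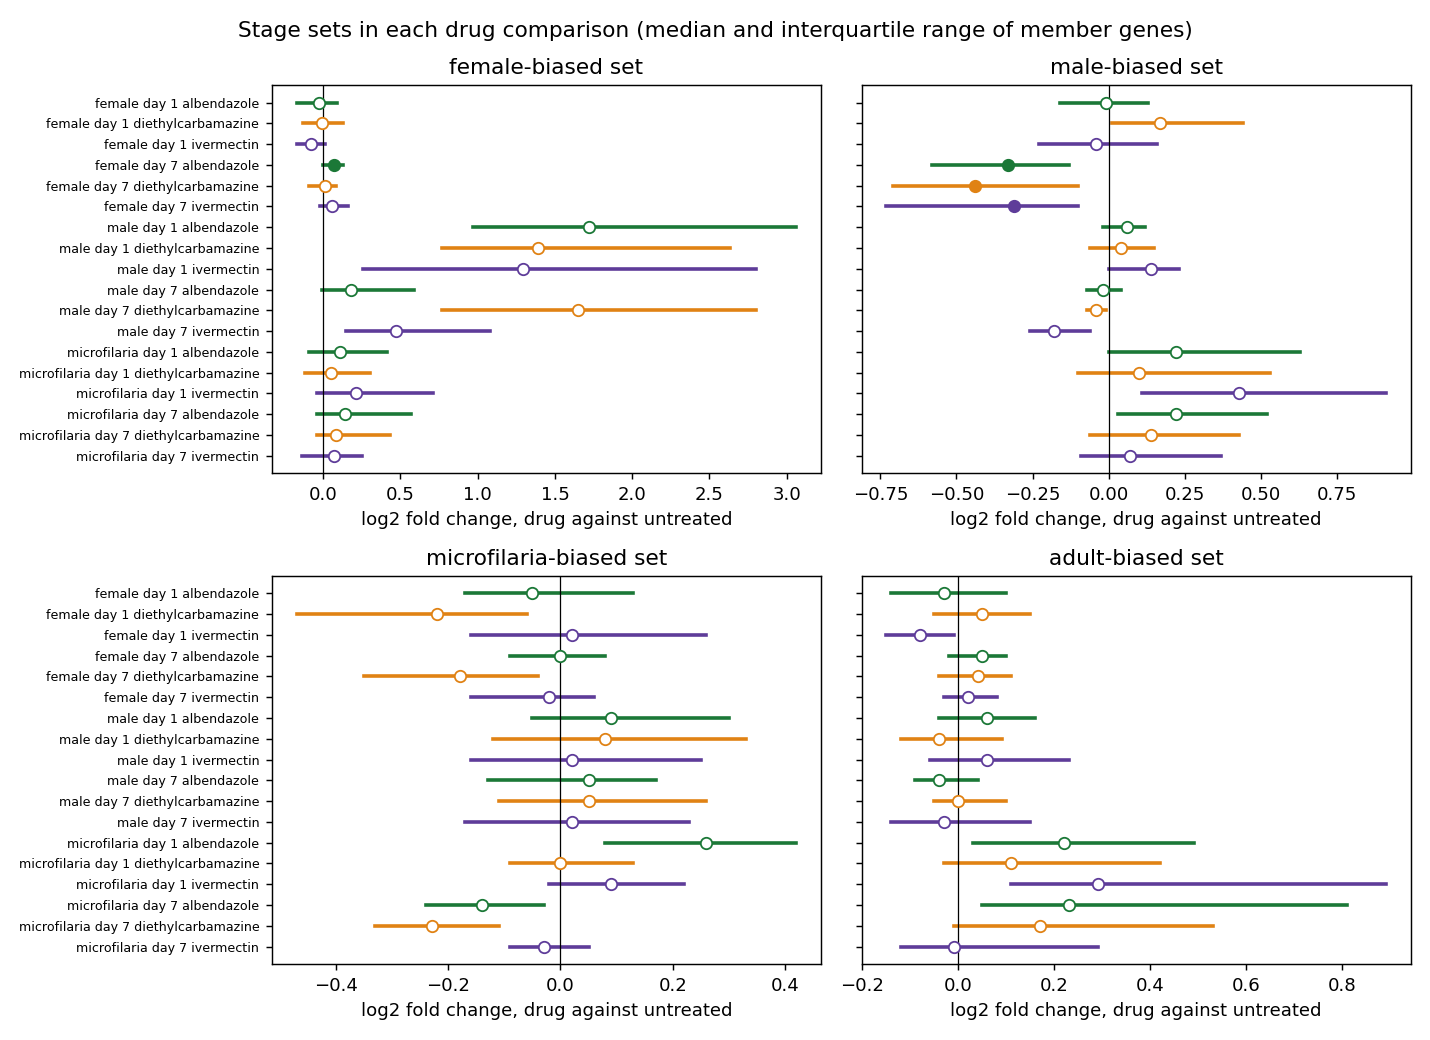
Log2 fold change of each drug against untreated worms for the genes of the 4 stage sets; points are medians over genes, lines interquartile ranges, and colour gives the drug. Filled points mark the 4 tests with an adjusted p under 0.05 by camera with an estimated correlation, all in day 7 females.

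In females, genes typical of males were lower 7 days after each drug, by an amount that depends on 1 untreated library. The male-biased set (93 genes) averaged 2.01 ± 0.36 log2 CPM in untreated day 7 females, 1.70 ± 0.03 with albendazole, 1.57 ± 0.14 with diethylcarbamazine and 1.66 ± 0.05 with ivermectin (SD, n = 3 each). The median log2 fold change was -0.33, -0.44 and -0.31 in that order, with 83, 79 and 80 of the 93 genes lower. All 3 were called by camera with the preset correlation (adjusted p = 2.91e-40, 3.14e-22 and 8.39e-31) and with an estimated correlation (adjusted p = 0.00145, 0.0174 and 0.00506), but not by fry (adjusted p = 0.16, 0.118 and 0.117). The 9 drug libraries had set levels of 1.43 to 1.73, all below the 3 untreated ones, which serve all 3 comparisons. The 1.43 came from diethylcarbamazine replicate 2, the library with the fewest counts of all (2112032). Of the untreated libraries, replicate 2 stood at 2.42 against 1.76 and 1.85. Without untreated replicate 2 the medians were -0.10, -0.18 and -0.11, with 61, 66 and 60 of 93 genes lower. The preset camera calls then held (adjusted p = 0.000103, 3.58e-06 and 3.18e-06), and those with an estimated correlation ended (adjusted p = 0.384, 0.137 and 0.221). With a replicate block within day, the estimated-correlation p was 0.0152, 0.11 and 0.0414.

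In females at day 1 the male-biased set was instead higher with diethylcarbamazine (median 0.17, 70 of 91 genes, preset camera adjusted p = 9.92e-05, but 0.354 with an estimated correlation). That call ended without untreated replicate 3 (0.0812) and turned without diethylcarbamazine replicate 1 (0.806). The female-biased set was higher by a median of 0.07 with albendazole at day 7 (77 of 100 genes, camera adjusted p = 0.0245 with an estimated correlation, 0.0694 with the replicate block, fry 0.418). Without untreated replicate 2 the preset camera p for it was 0.0756. With diethylcarbamazine, genes typical of microfilariae, which females carry in the uterus, were lower at both days. The median log2 fold change was -0.22 at day 1 (75 of 92 genes lower, camera adjusted p = 1.89e-10) and -0.18 at day 7 (73 of 92, 5.21e-06), but not with an estimated correlation (adjusted p = 0.233 and 0.362). The day 7 call also ended without untreated replicate 3 (adjusted p = 0.089) or diethylcarbamazine replicate 1 (0.81). The day 1 levels were 2.99 ± 0.11 untreated and 2.73 ± 0.17 with diethylcarbamazine (SD, n = 3), and the groups include the replicate 3 libraries that stood apart. At an unadjusted edgeR p under 0.05 there were 83 genes with albendazole, 204 with diethylcarbamazine and 92 with ivermectin at day 1, and 76, 104 and 99 at day 7, where 513 of 10264 would be expected by chance from independent tests. This fit had no replicate block, while libraries of the same number deviate together, which can lower such counts. Counts below the expected number, here and in the other stages, are therefore not read as fewer changes than chance. DESeq2 called 0 in all 6.

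In males, the largest set differences were in genes typical of females. At day 1 the female-biased set stood at 1.30 ± 0.10 log2 CPM in untreated males, 2.54 ± 1.60 with albendazole, 2.25 ± 1.57 with diethylcarbamazine and 2.18 ± 1.48 with ivermectin (SD, n = 3). At day 7 it was 1.23 ± 0.04 untreated, 1.5 ± 0.28 with albendazole, 2.24 ± 1.76 with diethylcarbamazine and 1.80 ± 0.33 with ivermectin. Preset camera called the set higher in all 6 comparisons, with medians of 1.72, 1.39 and 1.29 at day 1 and 0.18, 1.65 and 0.47 at day 7. With an estimated correlation it was called in none of them (adjusted p = 0.567, 0.841, 0.631, 0.863, 0.186 and 0.828). In 4 of the 6 groups 1 library stood far above the others. Over 328 genes at least 16-fold higher in untreated females, the excess above untreated males was 10.33% of the female level in albendazole day 1 replicate 1, 8.52% in diethylcarbamazine day 1 replicate 1, 10.04% in diethylcarbamazine day 7 replicate 1 and 3.1% in ivermectin day 1 replicate 2 (medians). Every other male library lay between -0.16% and 0.76%. Leaving out that library alone ended the set's preset camera call in each of the 4 groups (adjusted p = 0.106 with albendazole at day 1, 0.459 and 0.831 with diethylcarbamazine at day 1 and day 7, and 0.778 with ivermectin at day 1). Without all 4 libraries the set was still called higher by preset camera with albendazole at day 1 (adjusted p = 3.8e-08, but 0.264 with an estimated correlation), and it turned in the other 3 groups (0.307, 0.803 and 0.807).

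Smaller differences in the female-biased set remained in day 7 males whose groups hold none of these 4 libraries. With ivermectin the 3 libraries had set levels of 1.41, 1.99 and 1.99 log2 CPM, all above the untreated 1.26, 1.19 and 1.24. Their median excess over the 328 genes was 0.16%, 0.71% and 0.76% of the female level, against -0.08% to 0.01% untreated. For genes scarce, middling and abundant in females it was 0.53%, 0.82% and 0.67% in replicate 2. In replicate 3 it was 0.1%, 0.57% and 1.17%. Whether a small share of female RNA raised the set in these libraries was not tested. Ivermectin replicate 3 stands apart in other ways. Its 100 most abundant genes took 21.3% of counts, against 16.1% and 16.7% in replicates 1 and 2. Its TMM factor was 0.787, against 1.003 and 1.004. No fit left out both this library and the 4 above. Without the 4 libraries elsewhere in the fit the set was called higher there by preset camera (adjusted p = 8.04e-17) and with an estimated correlation (adjusted p = 0.047), but not by fry (0.0539). With albendazole the levels were 1.49, 1.23 and 1.79, and without the 4 libraries the adjusted p was 1.62e-09 by preset camera and 0.191 with an estimated correlation. With all libraries in the fit, the preset call ended without albendazole replicate 3 (0.306) or ivermectin replicate 2 (0.0565).

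**Figure D4:**
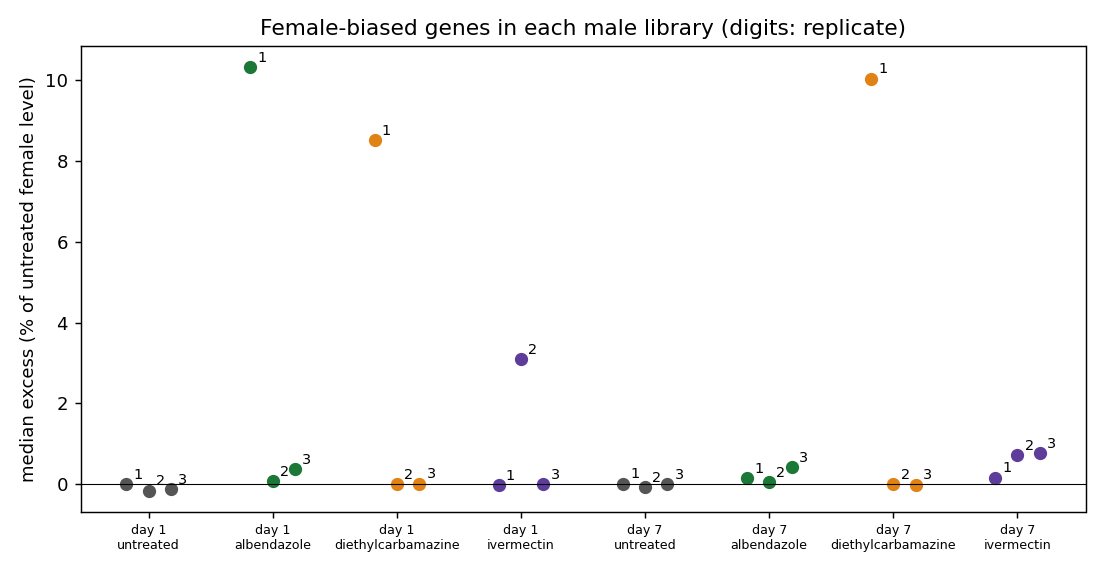
Median excess of 328 female-biased genes in each male library over the untreated male mean, in percent of the untreated female level; 1 point per library, digits give the replicate. The 6 untreated libraries lie between -0.16% and 0.01%, and 4 drug libraries between 3.1% and 10.33%.

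In males the medians of the male-biased set ran from -0.18 to 0.14 over the 6 comparisons. With ivermectin it had a median of 0.14 at day 1 (76 of 100 genes higher, preset camera adjusted p = 2.68e-05) and -0.18 at day 7 (84 lower, 4.8e-11), called in neither with an estimated correlation (adjusted p = 0.631 and 0.618). The day 1 value turned without untreated replicate 2 (adjusted p = 0.329). Preset camera also called the set higher with albendazole at day 1 (median 0.06, 69 of 100 genes, adjusted p = 0.018, but 0.627 with an estimated correlation) and lower with diethylcarbamazine at day 7 (median -0.04, 80 genes, 0.00363, but 0.685). The albendazole call turned without untreated replicate 2 (called lower, 7.17e-06) and ended without albendazole replicate 2 (0.108) or 3 (0.366). The diethylcarbamazine call turned without untreated replicate 1 (0.434) or diethylcarbamazine replicate 1 (0.831) and ended without diethylcarbamazine replicate 2 (0.25). At an unadjusted edgeR p under 0.05 there were 268 genes with albendazole, 470 with diethylcarbamazine and 929 with ivermectin at day 1, and 42, 86 and 578 at day 7, where 517 of 10347 would be expected. The day 1 counts rest on 1 untreated library: without untreated replicate 1, edgeR called 76 genes with albendazole (74 higher, 2 lower), 201 with diethylcarbamazine (199 and 2) and 324 with ivermectin (293 and 31). Of the 293 higher genes, 240 were also called higher in untreated males than in untreated females, at any fold change. Without the 4 male libraries named above, edgeR still called 0 genes in all 6 comparisons.

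In microfilariae, genes typical of adult worms were higher 1 day after each drug by preset camera, with the largest medians after ivermectin, but not in replicate 3. With ivermectin the male-biased set had a median log2 fold change of 0.43 (76 of 92 genes higher, preset camera adjusted p = 3.18e-08), the adult-biased set 0.29 (74 of 91, 8.65e-08) and the female-biased set 0.21 (67 of 92, 0.000324). The adjusted p was 0.235 for each with an estimated correlation and 0.168 by fry. With the replicate block fry called the male-biased and female-biased sets (adjusted p = 0.0428 each) but not the adult-biased set (0.0722), and the estimated correlation called none of the 3 (0.158, 0.158 and 0.193). With albendazole the male-biased and adult-biased medians were both 0.22 (70 of 92 and 71 of 91 genes higher, preset camera adjusted p = 0.000635 each), and with diethylcarbamazine 0.10 and 0.11 (56 of 92 and 62 of 91, 0.0014 and 0.000127). The female-biased set was called with neither (preset camera adjusted p = 0.22 and 0.244). With an estimated correlation the adjusted p was 0.479 for both sets with albendazole and 0.69 for both with diethylcarbamazine. Preset calls ended without albendazole replicate 1 (0.178 for both sets) or diethylcarbamazine replicate 1 (0.273 male-biased, 0.126 adult-biased), and the male-biased one also without untreated replicate 3 (0.084, diethylcarbamazine). Albendazole also had a microfilaria-biased median of 0.26 (81 of 100 genes higher, preset camera adjusted p = 2.09e-08, but 0.479 with an estimated correlation). The microfilaria-biased call ended without albendazole replicate 1 (0.176) or untreated replicate 2 (0.0572). The adult-biased set averaged 1.69 ± 0.12 log2 CPM untreated, 1.92 ± 0.40 with albendazole, 1.87 ± 0.32 with diethylcarbamazine and 2.09 ± 0.54 with ivermectin (SD, n = 3), so the drug libraries varied more than the untreated ones. In replicate 3 it stood at 1.47, 1.51 and 1.52 with the 3 drugs, below the untreated 1.64, and the male-biased set at 1.25, 1.35 and 1.32, below the untreated 1.41. At day 1 edgeR gave 503 genes with albendazole, 116 with diethylcarbamazine and 824 with ivermectin at an unadjusted p under 0.05, where 509 of 10174 would be expected, and DESeq2 called 0.

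The fit with a replicate block within day, added after the data were seen, called 18 genes with day 1 ivermectin in microfilariae by edgeR, 14 higher and 4 lower. Of the 18, 10 were called higher in untreated adults than in untreated microfilariae, 2 were called lower, and 4 were not in that test. Over all genes tested there, 4127 of 10633 were called higher in adults. The untreated day 1 microfilariae enter both comparisons, so the tally is not independent of the calls. WBGene00268870 had 45, 36 and 4 counts in ivermectin replicates 1 to 3 and 0, 2 and 0 in untreated ones, with an edgeR adjusted p of 0.0192 in that fit. WBGene00230512 had 41, 23 and 1 counts against 1, 0 and 1 (edgeR adjusted p = 0.0208). Among the lower genes, WBGene00230091 stood at 3.79 ± 0.61 log2 CPM against 4.61 ± 0.28 untreated, with a log2 fold change of -0.82 (SE 0.13, edgeR adjusted p = 0.0192). WBGene00225076 stood at 6.40 ± 0.40 against 7.02 ± 0.23, with -0.62 (SE 0.11, edgeR adjusted p = 0.0221). Without the block the edgeR adjusted p was 0.547 for each of these 4 genes, which were chosen after their values were seen.

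In day 7 microfilariae, with 2 libraries per group, genes typical of microfilariae were lower with diethylcarbamazine. The microfilaria-biased set averaged 6.73 ± 0.01 log2 CPM untreated and 6.48 ± 0.06 with diethylcarbamazine (SD, n = 2), a median log2 fold change of -0.23 with 86 of 100 genes lower (preset camera adjusted p = 6.11e-15, but 0.34 with an estimated correlation). With albendazole the set's median was -0.14 (79 of 100 lower, 9.42e-08, and 0.223 with an estimated correlation), and without albendazole replicate 2 the preset camera p was 0.141. At day 1 the albendazole median was 0.26, and the difference between days was not tested for sets. Genes typical of adults were higher with both drugs by preset camera. With albendazole the adult-biased, male-biased and female-biased medians were 0.23, 0.22 and 0.14 (adjusted p = 1.03e-08, 1.03e-05 and 0.000717, but 0.223 each with an estimated correlation). Without albendazole replicate 2 these calls ended (0.398, 0.866 and 0.398), and the male-biased set turned. With diethylcarbamazine the medians were 0.17, 0.14 and 0.08 (adjusted p = 0.000859, 0.00596 and 0.0304, but 0.403 each with an estimated correlation). These calls ended without diethylcarbamazine replicate 2 (0.421, 0.0632 and 0.301), the last 2 also without untreated replicate 1 (0.147 each), and the female-biased one without untreated replicate 2 (0.0904).

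WBGene00220302, the microfilarial gene named above, stood at 6.71 ± 0.09 log2 CPM with diethylcarbamazine and 8.90 ± 0.16 untreated, a log2 fold change of -2.19 (SE 0.67, edgeR adjusted p = 1). It was singled out after its values were seen. In untreated day 1 microfilariae it stood at 6.93 ± 0.66 log2 CPM (SD, n = 3), below the untreated day 7 level. For this gene the day 7 effect of diethylcarbamazine minus its day 1 effect, not called by edgeR after adjustment, was -3.72 (SE 0.86). That is further below 0 than the day 7 effect, so the gene was not lower with diethylcarbamazine at day 1. With ivermectin the set medians at day 7 ran from -0.03 to 0.07, with an adjusted p of 0.772 for each with an estimated correlation. The edgeR counts at an unadjusted p under 0.05 were 76, 77 and 33 for albendazole, diethylcarbamazine and ivermectin, where 509 of 10174 would be expected, and DESeq2 called 0 in each.

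Untreated worms of day 7 and day 1 were compared as background. EdgeR called 0 genes in each stage, with 288 genes at an unadjusted p under 0.05 in females, 976 in males and 70 in microfilariae. DESeq2 called 1 gene in males, WBGene00226722 (log2 fold change 0.50, SE 0.11, DESeq2 adjusted p = 0.0257; named after its value was seen), and 0 in the other stages. Without male day 1 untreated replicate 1, edgeR called 503 genes in males. No drug's effect differed between days in any gene by edgeR (0 calls in all 9 tests of the difference). The unadjusted counts for albendazole, diethylcarbamazine and ivermectin were 39, 104 and 40 in females, 125, 200 and 1177 in males, and 78, 62 and 77 in microfilariae. DESeq2 called 20 genes for ivermectin in males and 0 in the other 8 tests, and edgeR called 400 there without male day 1 untreated replicate 1.

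The drugs' effects were also compared between females and males. EdgeR called 0 genes in the 6 tests of the difference, with 230, 490 and 466 genes at an unadjusted p under 0.05 for albendazole, diethylcarbamazine and ivermectin at day 1 and 209, 258 and 277 at day 7. DESeq2 called 3 genes for albendazole at day 7 and 0 in the other 5 tests. The 3 were WBGene00221446, WBGene00229431 and WBGene00268662, each lower for the female minus the male effect with a DESeq2 adjusted p of 0.0421, and named after their values were seen. They are abundant in males, with 377 to 2045 counts in the untreated day 7 male libraries and 705 to 2611 with albendazole. In day 7 females the counts in untreated replicates 1 to 3 were 0, 15 and 0 for WBGene00221446, 3, 20 and 0 for WBGene00229431 and 3, 25 and 4 for WBGene00268662. Among the untreated females the high counts thus lie in replicate 2. Whether the male libraries add to the difference was not tested. With albendazole the female counts were 0, 0 and 0 for WBGene00221446, 3, 0 and 0 for WBGene00229431 and 5, 6 and 4 for WBGene00268662. Without female day 7 untreated replicate 3, edgeR called 40 genes for albendazole and 15 for ivermectin at day 7. Without male day 1 untreated replicate 1 it called 2 for ivermectin at day 1.

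The 3 drugs share their untreated libraries, so their fold changes covary without any effect. In day 1 males the covariance across genes was 0.073, 0.077 and 0.074 for the 3 pairs of drugs, against 0.043, 0.042 and 0.043 in simulated unchanged groups. In day 1 microfilariae it was 0.053 for albendazole with diethylcarbamazine, 0.1 for albendazole with ivermectin and 0.071 for diethylcarbamazine with ivermectin, against 0.046, 0.046 and 0.045. In females the covariances lay below the simulated ones at both days, from 0.003 to 0.035 against 0.07 to 0.071. In day 7 males they ran from 0.01 to 0.024 against 0.042 to 0.043, and in day 7 microfilariae from 0.05 to 0.085 against 0.068. The corresponding correlations ran from 0.03 to 0.76 and the simulated ones from 0.47 to 0.53. The simulated groups carry no replicate effect, while same-numbered libraries deviate together in these data, so the simulated values are not those of unchanged groups in this paired design and no shared effect is read from the differences. The untreated libraries, at most 3 per group, were not split between drugs. Because edgeR called 0 genes for each drug, 0 calls were shared. Without male day 1 untreated replicate 1 the shared calls were 71, 74 and 170 for albendazole with diethylcarbamazine, albendazole with ivermectin and diethylcarbamazine with ivermectin.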

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

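The tests of female-minus-male differences in stage sets, and all 4 tests of female-biased transcripts below, were chosen after the result was seen; the division of the 4 male libraries into 3 and 1 was also made then.

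A difference between the sexes in a drug's effect was called for 15 of 24 tests of a stage set by camera with the preset correlation, 1 with an estimated correlation and 0 by fry. Values are medians of the female effect minus the male effect on the log2 scale. For the female-biased set they were -1.69 (albendazole), -1.44 (diethylcarbamazine) and -1.34 (ivermectin) at day 1, and -1.65 (diethylcarbamazine) and -0.37 (ivermectin) at day 7. For the male-biased set they were 0.20 (diethylcarbamazine) and -0.13 (ivermectin) at day 1, and -0.34 (albendazole), -0.46 (diethylcarbamazine) and -0.22 (ivermectin) at day 7. For the microfilaria-biased set diethylcarbamazine gave -0.29 at day 1 and -0.32 at day 7. For the adult-biased set they were 0.10 (diethylcarbamazine) and -0.12 (ivermectin) at day 1, and 0.08 (albendazole) at day 7. The one called with an estimated correlation was the male-biased set with albendazole at day 7 (-0.34, 87 of 100 genes lower, adjusted p = 0.0245, fry 0.284), where female untreated replicate 2 has a high level of that set (2.42 against 1.76 and 1.85 log2 CPM).

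In 4 of the 5 female-biased differences the male group holds a library with a large excess of female-biased transcripts, 3 of them of replicate 1 and the other ivermectin day 1 replicate 2; the day 7 ivermectin difference holds none of them and was not weighed. In none of them was the median excess near that of a female library under a male label, the highest being 10.33% of the female level, and a drug effect of that size shared by the group was argued against too, since 2 of the 8 other libraries of the same groups lay above the highest untreated library (0.01%), but these are both of the other albendazole day 1 libraries, at 0.08% and 0.37%, so a smaller rise shared by that group stays open. In the 3 replicate 1 libraries the excess was a like share of the female level for genes scarce and abundant in females, the highest ratio between tertiles of abundance being 1.26, so female RNA or reads in those libraries is a candidate explanation. In ivermectin day 1 replicate 2 the share rose from 0.85% in the lowest to 11.63% in the highest tertile, a ratio of 13.63, which argues against a uniform share of female RNA there. What raised its female-biased genes, such as part of a female's tissue or a response in 1 animal's worms, was not tested.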

How the results depend on the processing

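Set tests without single libraries, the replicate block within day and the fits without doubted libraries were chosen after the result was seen; the other alternatives were planned. RLE size factors in edgeR, no filter on low counts and the replicate block changed no count of called genes by over 1.5 times, and the first and last of these ended none of the 38 set calls by camera with the preset correlation. DESeq2 called 1 gene in place of 0 for male day 1 diethylcarbamazine, 1 for male untreated day 7 against day 1, 20 for the male ivermectin difference between days and 3 for the day 7 albendazole difference between sexes. The replicate block within day gave 18 genes for microfilaria day 1 ivermectin. Of the 38 set calls in drug comparisons, 4 held with an estimated correlation and 0 by fry. The replicate block ended 1 of those 4 (female-biased set, female day 7 albendazole, 0.0694) and brought fry to 0.0428 for the female-biased and male-biased sets of microfilaria day 1 ivermectin; it changed no other call. Within day, it ended that call (0.169) and that of the male-biased set in female day 7 diethylcarbamazine (0.11), gave 0.0483 by fry for the same 2 sets, and brought the microfilaria-biased set of microfilaria day 1 ivermectin to 0.0209 by preset camera.

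Leaving out each library in turn gave 0 to 76, 0 to 201 and 0 to 324 genes for day 1 males with albendazole, diethylcarbamazine and ivermectin. It gave 0 to 503 for male untreated day 7 against day 1, 0 to 400 for the male ivermectin difference between days and 0 to 2 for the day 1 ivermectin difference between sexes. Shared calls in day 1 males ranged from 0 to 71, 0 to 74 and 0 to 170. Each of these highest values came without male day 1 untreated replicate 1. The day 7 differences between sexes gave 0 to 40 (albendazole) and 0 to 15 (ivermectin), the highest without female day 7 untreated replicate 3.

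For the 38 set calls, 165 of 212 values without 1 library kept the call, 37 lost it and 10 turned; at least 1 library ended or turned 29 of the 38. Ranges of the camera adjusted p for sets that turned were as follows. In day 1 females with ivermectin the female-biased set ran from 6.09e-05 to 0.737 and the adult-biased set from 0.000184 to 0.737, turned without ivermectin replicate 3, and both were 0.81 without the 3 female libraries that stood apart. That fit also called the microfilaria-biased set there lower (0.00052, higher and not called at 0.22 with all libraries), and ended the estimated-correlation call of the male-biased set in female day 7 diethylcarbamazine (0.0992). RLE size factors added a call of the adult-biased set in female day 1 diethylcarbamazine (0.0461). The male-biased set in day 1 females with diethylcarbamazine ran from 7.9e-10 to 0.806, turned without diethylcarbamazine replicate 1. In day 1 males the female-biased set ran from 3.72e-21 to 0.459 with diethylcarbamazine and from 2.46e-12 to 0.778 with ivermectin, turned without diethylcarbamazine replicate 1 and ivermectin replicate 2. Without the 4 male libraries with female-biased transcripts these were 0.307 and 0.807, the female-biased set stayed called with albendazole at day 1 (3.8e-08) and day 7 (1.62e-09) and with ivermectin at day 7 (8.04e-17), and in day 7 males with diethylcarbamazine the female-biased and male-biased sets both turned, at 0.803. The male-biased set in day 1 males ran from 1.46e-07 to 0.366 with albendazole (turned without untreated replicate 2, 7.17e-06) and from 3.75e-10 to 0.329 with ivermectin (turned without untreated replicate 2). In day 7 males with diethylcarbamazine it ran from 6.37e-13 to 0.831, turned without untreated replicate 1 (0.434) or diethylcarbamazine replicate 1. In day 7 microfilariae with albendazole it ran from 2.1e-09 to 0.866, turned without albendazole replicate 2, which leaves 1 library that is assumed to vary like those of the other groups. Where the libraries' own levels are not given above, the cause was not tested. Depth was at least 2112032 counts per library. Simulated 2-fold changes were called in 38.2% (female day 1 diethylcarbamazine) and 69.1% (male day 1 ivermectin) of changed genes, with no replicate effect simulated. Changes of 2-fold or less are therefore not excluded, and larger ones can be missed too.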

Other observations

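The test of an effect of ivermectin alone in day 1 males was chosen after the result was seen, as was the fit with a replicate block within day.

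Scarce transcripts were most abundant in some drug-exposed microfilaria libraries. The 809 genes under 1 CPM in untreated day 1 microfilariae took 0.188% and 0.108% of counts in ivermectin replicates 1 and 2, 0.085% and 0.085% in those of albendazole and 0.092% and 0.065% in those of diethylcarbamazine, against 0.036% and 0.058% in untreated replicates 1 and 2. In replicate 3 the share was 0.038%, 0.035%, 0.035% and 0.039% in the same order, so that round shows no difference. At day 7 the shares were 0.042% and 0.045% untreated, 0.064% and 0.085% with albendazole, 0.063% and 0.062% with diethylcarbamazine and 0.074% and 0.04% with ivermectin. The genes were chosen for low levels in the untreated day 1 libraries themselves, and kept only where some microfilaria libraries held enough counts. That choice favours a higher share in all other libraries, so the rise is not measured free of it. All 18 genes called with day 1 ivermectin under the replicate block within day had the same direction with albendazole and with diethylcarbamazine at day 1, and 16 had it with ivermectin at day 7, without a test of that overlap beyond the shared untreated libraries.

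A small uniform share of adult worm material in the ivermectin libraries would give a like share for all genes. Over 774 adult-biased genes the excess was 4.408% of the adult level for genes scarce in adults and 0.595% for abundant ones, a ratio of 7.41. However, the untreated libraries that are subtracted also helped choose the genes, and untreated replicate 2 alone gave 0.767% and 0.233%. Ivermectin replicate 3, averaged in, held no excess (median -0.209%). The ratio therefore cannot decide on adult material, and material of 1 sex was not tested. A background that lifts all scarce transcripts cannot be told apart from a change in adult-type genes. Among the 809 scarce genes the 268 not adult-biased had a median log2 change of 0.45 and the 541 adult-biased 1.63, a ratio of 0.28 that lies between the bounds set beforehand. The untreated day 1 microfilariae served both to choose the scarce and adult-biased genes and to measure their change. Chance low values there raise these medians, so the ratio is not independent of the choice. A response of the larvae to the drug stays open, untested. The scarce share and the levels of the adult-biased and male-biased sets do not show it in replicate 3. Of the 18 genes called with the block within day, 13 had the same direction in all 3 replicate pairs. They were picked with those same libraries, so that tally is favoured by the choice.

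In day 1 males the count of called genes depended on untreated replicate 1. For the 324 genes called with ivermectin without it, the mean signed deviation from all male libraries was 0.16 in that library, -0.54 and -0.80 in untreated replicates 2 and 3, and between -0.23 and 0.26 in the other male libraries; of the 293 higher genes, 81.9% were called higher in untreated males than in untreated females at any fold change, against 37% of all genes. A swap with a drug library of the same round is argued against, since exchanging them gave 0 calls for all 3 drugs, but a swap between rounds stays open, since exchanging it with ivermectin replicate 3 gave 403 genes and with albendazole replicate 2 gave 176. A few genes taking most of the counts are argued against by the 330 genes called without the 100 most abundant. For an effect of ivermectin alone, the median signed log2 change was -0.02 against untreated day 7 males and 0.72 against untreated day 1. That test assumes untreated males alike at both days. In the same fit 271 of the 324 genes were also called between untreated day 7 and day 1, in the same direction. The test therefore cannot decide on an effect of ivermectin alone. Whether untreated replicates 2 and 3 or replicate 1 represent day 1 males is open, and a response common to the 3 drugs at day 1 was not tested.

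Other splits of the libraries were counted for the comparisons given here. Drug, day and difference tests within microfilariae that use day 7, with 2 libraries per group, were not split. Females against males within drug groups were not split either. For untreated females against males, 1 of 100 drawn splits, the real one, gave as many as 7733 genes and the highest other split gave 4678. Chance is therefore unlikely, as far as 100 draws can tell. For untreated microfilariae against adults 1 of 100 did, with 7560 genes and 2548 in the highest other split. In the 17 comparisons of 3 libraries with 3 there are 10 splits, too few for a share under 0.05; the real value was 0 in each, so all 10 gave as many. The highest other split gave 0 genes in 13 of them. It gave 3100 for day 1 females with diethylcarbamazine and 1814 with ivermectin, where drug replicates 1 and 2 and untreated replicate 2 faced a group that held both replicate 3 libraries. It gave 176 for day 1 males with albendazole and 403 with ivermectin, where untreated replicate 1 stood with 2 drug libraries. The female counts point to a structure of the samples by replicate, and the male counts to the place of untreated replicate 1. Among splits that part all 3 pairs of replicate numbers, as the real one does, the highest other value was 0. For the 12 differences of effects between days or sexes, 10 splits were drawn each and all 10 gave as many as the real 0. The highest other split gave 10, 2310 and 783 genes for the day 1 differences between sexes with albendazole, diethylcarbamazine and ivermectin, and 0 for the other 9.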
